A study of Mus musculus with 6 samples.

How the data were processed

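RNA was measured in 6 samples of FACS-sorted mouse lung epithelial cells, 2 each of BASC, AT2 and Club cells, from mice aged 8 weeks. Libraries were made per the labels with a stranded total RNA kit for picogram inputs (SMARTer Stranded Total RNA, Pico) and sequenced in bulk. Per the submitters' processing notes, reads were checked with FastQC, aligned to mm10 (GRCm38) with STAR 2.4.0a and counted per gene with featureCounts 1.4.5-p1 of the Subread package. The normalization method, the strand setting and the annotation release are not given in the sources used here.

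The deposited table holds 1 signal value per gene and sample, which the authors made by scaling gene-level read counts with 1 factor per sample and rounding to whole numbers. This reading rests on the values: they are whole numbers, the median-ratio factors of the 6 columns lie between 1.02 and 1.03, and low whole numbers are missing or doubled at regular intervals that differ between samples. From these intervals, 1 read was worth 1.34 and 0.916 units in the BASC replicates, 0.764 and 1.07 in AT2, and 0.825 and 1.04 in Club cells. Estimated reads are the column totals divided by these values, so they cover only the genes in the table. The lowest maximum of any gene in the table was 7, so genes with lower values throughout are missing from it. Whole reads could not be recovered exactly where 1 read was worth less than 1 unit, so the count models of edgeR and DESeq2 were not run. The table held 22239 genes, of which 14861 were protein coding, and 13 symbols stood on more than 1 gene; for these the gene with the highest mean was used in gene lists. Of the gene identifiers, 99.8% were found in GENCODE mouse release 21 and 75.8% had the same coordinates there; coordinates in the text are those deposited.

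The make-up of the values was similar in the 6 samples. The 10 highest genes held between 28.5% and 30.8% of the values, ribosomal RNA genes with Gm23935 and Gm26917 held between 17.1% and 21.1%, and the mitochondrial chromosome held between 9.76% and 11.1%. Pearson's r of log2 values between replicates, across genes, which are not independent replicates, was 0.857 in BASC, 0.872 in AT2 and 0.925 in Club cells. For genes with a mean over 1000 the median absolute log2 difference between replicates was 0.17, 0.19 and 0.13, and for genes with a mean of 10 to 100 it was 1.22, 1.19 and 0.71, so genes with few reads carry wide errors. Floors of 3 reads per library, averaged over a group, stand in for a group listed at 0, and such folds are given as lower bounds that cover counting error only.

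Values were analysed as log2(value + 1). Genes with at least 10 in at least 2 samples were kept, which left 17721 genes, 13369 of them protein coding. The 6 samples were fitted together by group in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), so that the groups shared 1 estimate of the spread per gene, with 3 residual and 4.20 prior degrees of freedom. Tests were 2-sided, p-values were adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. Adjusted p-values of genes and SE are those of the moderated fit, with 2 samples per group. Fold changes in the text are ratios of group means, and log2 fold changes are those of the fit. The position of BASC was computed per gene as the log2 distance from Club cells over the distance between AT2 and Club cells, for genes called between the latter with an absolute log2 fold change of at least 2. Shares of the Club or AT2 level were computed on the unlogged values after subtraction of the level in the other population, for genes with a mean of at least 5000 and a log2 fold change of at least 3.

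The 34 gene lists held 561 genes, of which 471 were tested. Each list with at least 5 tested members was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, with adjustment over the lists of a comparison. Calls adjusted over the list alone repeat the Benjamini-Hochberg step within the list. Of lists past the threshold at the preset correlation, 11 in BASC against AT2, 17 in BASC against Club cells and 15 in AT2 against Club cells, 2, 3 and 3 passed with an estimated correlation. Lists also lost their pass where the estimate lay under the preset 0.01. In BASC against Club cells, these included the goblet list (estimate -0.085, camera adjusted p from 5.49e-05 to 0.100) and the tight junction list (-0.052, from 0.00625 to 0.147). A lost pass is therefore not by itself a sign of high correlation between the genes of a list. The gene lists, the groups, the tests, the threshold and the rule for naming genes were fixed before the data were examined. The rule named Sftpc and Scgb1a1, up to 10 genes per direction with the largest fitted change among called genes with a mean of at least 100 in the higher group, a symbol that is not a predicted-gene name, and no overlap between the samples, up to 4 called members per list with the smallest adjusted p (or up to 2 with the highest mean where none was called), and up to 15 genes per direction for BASC against both. Some genes that the rule named are not reported here. Muc1, Cbr2, Gstt1, Lyz2, Aox3, Btbd11, Btc, Clic3, Otud1, Palm2 and Pkib were named after their values were seen.

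The fit was tested on simulated data with 200 changed genes in each of 5 runs, drawn from the spread between replicates. Of built-in changes of 4-fold, 57.6% were recovered for BASC against AT2, 60.0% for BASC against Club cells and 71.6% for AT2 against Club cells, and between 1.23% and 2.45% of calls were false. In 100 simulations of groups without a difference, at most 1 gene was called per direction in any comparison. In these and the other simulations, genes of equal mean were given the same spread. Genes with a wider spread of their own were thus left out, so the error rates need not hold in the data. Alternatives changed 1 choice at a time: the pseudocount, the filter, the scaling, the samples in the fit, the prior, sample weights, a replicate block, leaving out each sample, and the correlation in the list test. A fit with voom weights on the estimated reads was added after seeing the data. Trimmed-mean scaling followed the published method with 30% of ratios and 5% of levels trimmed at each end. Scaling to a common total shifted the median of all genes by -0.11 on the log2 scale in AT2 against Club cells, and quantile normalization shifted it by 0.14 in BASC against Club cells and 0.20 in AT2 against Club cells. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.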

Results

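RNA was sequenced in bulk from 3 populations of lung epithelial cells of mice aged 8 weeks, with 2 samples in each. Bronchioalveolar stem cells (BASC) carried both fluorescent reporters used for sorting, CCSP-mCherry for the club cell secretory protein gene Scgb1a1 and SPC-YFP for the surfactant protein C gene Sftpc. Alveolar type 2 (AT2) cells, which make surfactant, were sorted as SPC-YFP positive, and Club cells, the secretory cells of the bronchioles, as CCSP-mCherry positive. Lungs had been depleted of cells bearing CD31 or CD45 before the sort. The deposited table held normalised read counts of 22239 genes in 6 samples. From the spacing of the low values, the reads over the genes in this table were estimated at 10121884 and 14716169 in BASC replicates 1 and 2. The estimates were 18203252 and 13172351 in the AT2 replicates, and 15437848 and 12724381 in the Club replicates. A value of 3 reads, the limit that a count of 0 allows, came to between 2.29 and 4.02 normalised counts in these samples, which covers counting error only. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples.

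The reporter genes followed the sort labels. The sort selected for each reporter gene, so its difference from the population without that reporter checks the labels and is not a finding. Sftpc (ENSMUSG00000022097, GRCm38 chromosome 14, 70520941 to 70524081) had normalised counts of 290809 and 307458 in BASC, 301267 and 373742 in AT2, and 240 and 224 in Club cells. Scgb1a1 (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958) had 43993 and 58791 in BASC, 413 and 302 in AT2, and 751642 and 760675 in Club cells. BASC thus held Sftpc at 88.6% of its AT2 level and Scgb1a1 at 6.80% of its Club level. Across all genes tested, the first principal component took 49.7% of the variance and the second 16.7%. On the first, BASC lay at -45.3 and -49.0, AT2 at -115 and -127, and Club cells at 171 and 165. On the second, BASC replicate 1 lay at 31.9 and BASC replicate 2 at 141. Pearson's r between the BASC replicates, 0.857, was little above that of BASC replicate 1 with each AT2 replicate, 0.851.

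**Figure D1:**
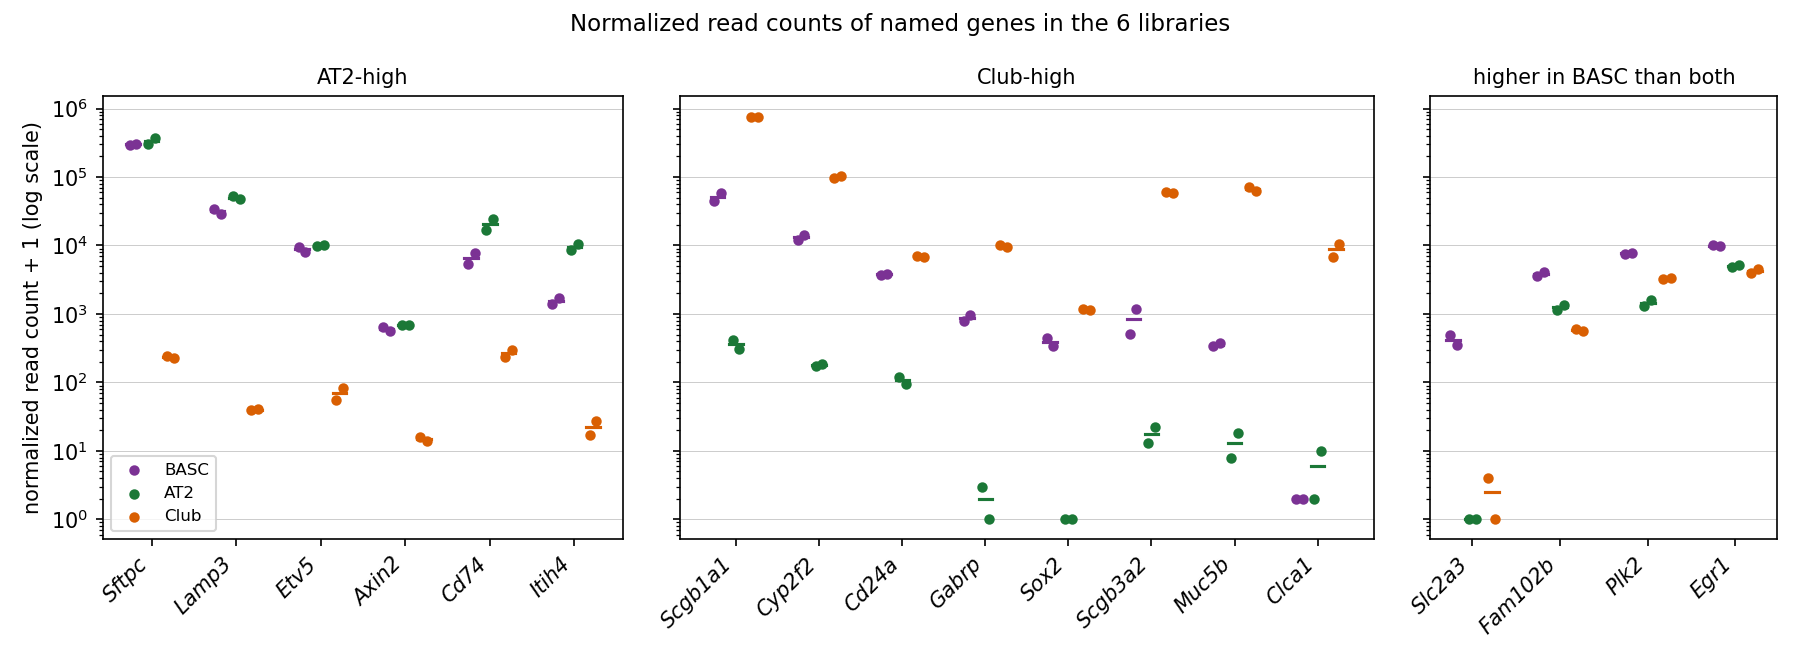
Normalised read counts of named genes in each of the 6 libraries on a log axis (value + 1); points are libraries and bars are group means. Sftpc lay near its AT2 level in BASC, while Scgb1a1 lay between its levels in AT2 and Club cells.

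BASC were compared with AT2 cells to ask which genes differ between cells carrying both reporters and cells sorted on SPC-YFP. BASC had higher levels of genes of the Club cell programme, while the surfactant protein genes Sftpa1 and Sftpc were not called. Scgb1a1 was 144-fold higher in BASC than in AT2 (log2 fold change 7.17 ± 0.18, SE, n = 2 per group, limma adjusted p = 1.03e-05). The sort on CCSP-mCherry selected for this difference, so it is not a finding about the programme. Cyp2f2, a cytochrome P450 of Club cells that activates naphthalene, was 73.0-fold higher (6.18 ± 0.13, adjusted p = 3.82e-06), with 11815 and 14384 normalised counts in BASC against 173 and 186 in AT2. Cd24a, a surface glycoprotein gene, was 35.6-fold higher in BASC (adjusted p = 2.57e-05). Sftpa1 had 230819 and 245719 in BASC and 238017 and 238052 in AT2 (adjusted p = 1), and Sftpc differed by a log2 fold change of -0.17 ± 0.12 (adjusted p = 0.635). Of 17721 genes tested, 98 were higher and 14 lower in BASC.

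Of 25 Club secretory markers tested, 10 were higher in BASC than in AT2 and 15 were not called; 15 were higher when adjusted over the list alone. The list's median log2 fold change was 1.54 (camera adjusted p = 3.90e-23, and adjusted p = 0.0390 with an estimated correlation). Beyond Scgb1a1 and Cyp2f2, they included Gabrp, a subunit of the GABA-A receptor, at 789 and 954 in BASC against 2 and 0 in AT2 (adjusted p = 0.000700). They also included Sox2, a transcription factor of the conducting airway, at 438 and 343 in BASC and listed at 0 in both AT2 libraries, which is at least 142-fold higher (adjusted p = 0.000934). Of 28 genes of xenobiotic metabolism, 11 were higher in BASC and 17 were not called, with 20 higher when adjusted over the list alone. Their median log2 fold change was 1.62, or 1.60 with genes at 0 set to their bound (camera adjusted p = 2.94e-24, and adjusted p = 0.0390 with an estimated correlation). The retinaldehyde dehydrogenase gene Aldh1a1 was 38.7-fold higher (adjusted p = 0.00372), the flavin monooxygenase gene Fmo2 was 6.20-fold higher (adjusted p = 0.00443), and Aldh1a7 was 2.42-fold higher (adjusted p = 0.00476). Aldh1a1 and Aldh1a7 are close paralogs, so the split of reads between them is uncertain. The xenobiotic list shares Cyp2f2, Cbr2, Aldh1a1 and Aldh1a7 with the Club secretory list.

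Among genes with the largest differences, several had almost no reads in AT2. Kdr, known as the VEGF receptor of endothelial cells, had 689 and 517 in BASC, 1 and 0 in AT2, and 5510 and 5892 in Club cells (BASC against AT2, adjusted p = 0.000502). Of 8 endothelial markers tested, Kdr was the only gene called in this comparison. Slc2a3, a glucose transporter gene, had 494 and 349 in BASC and was listed at 0 in AT2, which is at least 153-fold higher (adjusted p = 0.0272). The glycosyltransferase gene Mgat3 was at least 110-fold higher, the amino acid transporter gene Slc38a1 at least 105-fold and the metalloprotease gene Adam28 at least 104-fold, each listed at 0 in both AT2 libraries. Enah, an actin regulator, Gfra1, a GDNF co-receptor, and Parm1 were also among the 10 largest differences, with adjusted p from 0.000502 for Enah to 0.00592 for Parm1. Hes1, a target of Notch signalling, was 1.97-fold higher in BASC (adjusted p = 0.0283), and the Notch list had a median log2 fold change of 0.35 (camera adjusted p = 0.0102, and adjusted p = 0.240 with an estimated correlation). The Wnt list lay lower in BASC, with a median of -0.25 (camera adjusted p = 0.0334, and adjusted p = 0.372 with an estimated correlation). Of its 23 genes tested, 6 had a positive difference. Limma called none of them, with 3 lower at an unadjusted p under 0.05. Creb3l1 (adjusted p = 0.0272) and the mucin gene Muc5ac (adjusted p = 0.0444) were higher among 7 goblet cell markers, a list that did not pass (camera adjusted p = 0.0605). The call of Muc5ac was lost in 11 alternatives. Pigr, which carries immunoglobulins across epithelia, was 6.49-fold higher (adjusted p = 0.0103), and Scnn1b, a sodium channel subunit gene, was 2.93-fold higher (adjusted p = 0.0414).

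Genes lower in BASC than in AT2 included antigen presentation genes. Of 7 genes of MHC class II presentation tested, 2 were lower in BASC and 5 were not called; 5 were lower when adjusted over the list alone. Cd74, the class II invariant chain, was 3.15-fold lower (log2 fold change -1.65, adjusted p = 0.0378), and Ciita, the class II transactivator, was 7.11-fold lower (adjusted p = 0.0465). The list's median was -1.96 (camera adjusted p = 1.49e-06, but adjusted p = 0.242 with an estimated correlation). Itih4, an acute phase protein gene, was 6.21-fold lower (adjusted p = 0.0103), with 1377 and 1682 in BASC and 8474 and 10524 in AT2. Cald1, an actin-binding protein gene, was 7.80-fold lower (adjusted p = 0.0233), with 1600 and 848 in the AT2 libraries. Bicc1, Heatr1, Sgpp2 and Fam184a were also lower, by between 3.18-fold for Fam184a and 5.71-fold for Bicc1. Among 26 AT2 markers limma called none over all genes, with 9 lower and 1 higher at an unadjusted p under 0.05, and 6 were lower when adjusted over the list alone. Their median log2 fold change was -0.18 (camera adjusted p = 5.01e-05, and adjusted p = 0.240 with an estimated correlation). Cholesterol synthesis genes, all 18 with a negative difference, had a median of -0.44 without a called gene; limma found 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.000605, and adjusted p = 0.571 with an estimated correlation). Srebf2, a regulator of that pathway, had 4479 and 3856 in BASC and 5630 and 5623 in AT2 (adjusted p = 0.208).

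The counts of this comparison rested on both BASC libraries: without BASC replicate 1 there were 3 genes higher and 0 lower, and without BASC replicate 2 there were 4 and 0, in fits where the remaining sample was assumed to vary like the other groups. Without AT2 replicate 1 or AT2 replicate 2 the genes lower in BASC numbered 2, and without Club replicate 1 or 2 they numbered 24 and 27. Of the 43 differences named in the text and called here that could be tested without a BASC library, 3 were still called without BASC replicate 1 (Scgb1a1, Cyp2f2 and Cd24a), and 4 without BASC replicate 2 (these genes and Mgat3). Of 44, 25 were still called without AT2 replicate 1 and 23 without AT2 replicate 2. At an unadjusted p under 0.05, limma found 1257 genes higher and 1079 lower. Changes of 4-fold built into simulated data were recovered in 57.6% of cases for this comparison, and changes of 2-fold in 10.4%, so a gene that was not called may still differ.

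BASC were compared with Club cells to ask which genes differ between cells carrying both reporters and cells sorted on CCSP-mCherry. Genes of the AT2 programme were higher in BASC, and genes of the secretory programme of Club cells were lower. Of 26 AT2 markers, 25 were higher in BASC and Muc1 was not called, with 26 higher when adjusted over the list alone. Their median log2 fold change was 4.03 (camera adjusted p = 5.87e-47, and adjusted p = 0.0289 with an estimated correlation). Sftpc, which the sort selected for, was 1289-fold higher (log2 fold change 10.33, adjusted p = 6.16e-08). Lamp3, a lysosomal protein gene of lamellar bodies, was 806-fold higher (adjusted p = 6.16e-08), and the phosphate transporter gene Slc34a2 was 84.6-fold higher (adjusted p = 5.69e-07). Hc, which encodes complement C5, was 177-fold higher (adjusted p = 6.16e-08). Of 25 Club secretory markers, 21 were lower in BASC and 4 were not called, with 24 lower when adjusted over the list alone. Their median was -3.50, or -3.33 with genes at 0 set to their bound (camera adjusted p = 4.38e-22, and adjusted p = 0.0289 with an estimated correlation). Scgb1a1 was 14.7-fold lower in BASC (log2 fold change -3.89, adjusted p = 3.93e-05), Cyp2f2 was 7.64-fold lower (adjusted p = 2.50e-05), and the mucin gene Muc5b was 188-fold lower (adjusted p = 4.01e-05). Chad, a matrix protein gene, had 19 and 14 in BASC against 5851 and 5040 in Club cells. Cd24a, by contrast, was 1.84-fold lower in BASC (adjusted p = 0.0142), and Sox2, 2.94-fold lower by its means, was not called (adjusted p = 0.114).

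Lipid and antigen presentation genes were higher in BASC than in Club cells. Of 20 genes of fatty acid and phospholipid synthesis, 11 were higher and 9 were not called; 12 were higher and 1 lower when adjusted over the list alone (median log2 fold change 1.24, camera adjusted p = 6.87e-11, but adjusted p = 0.125 with an estimated correlation). Fasn, the fatty acid synthase, was 11.9-fold higher (adjusted p = 2.00e-05), and Lpcat1, which makes the main surfactant phospholipid, was 37.6-fold higher (adjusted p = 4.44e-06). Of 18 cholesterol synthesis genes, 10 were higher and 8 were not called, with 13 higher when adjusted over the list alone (median 1.30, camera adjusted p = 3.15e-09, but adjusted p = 0.259 with an estimated correlation). Of 7 MHC class II genes, 5 were higher and 2 were not called, also when adjusted over the list alone (median 4.61, camera adjusted p = 6.07e-08, but adjusted p = 0.158 with an estimated correlation). H2-Eb1 was listed at 0 in both Club libraries and was at least 161-fold higher in BASC (adjusted p = 0.000156), while H2-Ab1 had 774 and 1568 in BASC against 0 and 1 in Club cells (adjusted p = 7.91e-05). Reads of class II genes can be shared between family members. Of 28 xenobiotic genes, 21 were lower in BASC and 7 were not called; 21 were lower and 1 higher when adjusted over the list alone (median -2.50, camera adjusted p = 3.43e-16, and adjusted p = 0.0490 with an estimated correlation). Por, the reductase that feeds electrons to cytochromes P450, was 4.56-fold lower (adjusted p = 5.61e-05), and the glutathione transferase gene Gsta3, which has close paralogs, was 9.52-fold lower (adjusted p = 6.81e-05).

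Signalling genes differed as well. Of 13 genes of the FGF pathway and its feedback, 8 were higher in BASC than in Club cells, 2 were lower and 3 were not called, with the same counts when adjusted over the list alone (median log2 fold change 1.10, camera adjusted p = 4.20e-05, but adjusted p = 0.239 with an estimated correlation). The transcription factor gene Etv5 was 128-fold higher (adjusted p = 7.10e-06), and the receptor gene Fgfr2 was 3.96-fold higher (adjusted p = 8.05e-05), with 21888 and 18913 in BASC against 4828 and 5475 in Club cells. Of 17 BMP and TGF-beta genes, 5 were higher and 12 were not called, also when adjusted over the list alone (median 0.47, camera adjusted p = 3.18e-05, but adjusted p = 0.100 with an estimated correlation). The ligand gene Bmp2 was 59.1-fold higher (adjusted p = 0.000503). Of 15 Notch genes, 5 were lower in BASC and 10 were not called; 7 were lower and 1 higher when adjusted over the list alone (median -0.60, camera adjusted p = 0.0226, but adjusted p = 0.187 with an estimated correlation). Notch2 was 1.99-fold lower (adjusted p = 0.00295), Notch3 was 22.1-fold lower (adjusted p = 0.00453) and Hes1 was 1.86-fold lower (adjusted p = 0.00598). Of 23 Wnt pathway genes, 7 were higher, 4 were lower and 12 were not called, with 8 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.123). The feedback genes Nkd1, at 3088 and 2886 in BASC against 0 and 1 in Club cells (adjusted p = 1.40e-05), and Axin2, 42.7-fold higher (adjusted p = 9.39e-05), were among those higher. Of 24 lung epithelial transcription factor genes, 8 were higher and 2 were lower (9 and 5 when adjusted over the list alone; camera adjusted p = 0.0320, or 0.139 under quantile normalization, but adjusted p = 0.319 with an estimated correlation). Nkx2-1, required for lung epithelial identity, was 2.27-fold higher in BASC (adjusted p = 0.000656).

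Further genes were also called against Club cells. The alarmin gene Il33 had 2361 and 1956 in BASC against 0 and 1 in Club cells (adjusted p = 1.52e-05), and the metalloprotease gene Adam19 had 3405 and 2964 against 0 and 4 (adjusted p = 0.000116). The lysozyme gene Lyz1, whose reads can be shared with Lyz2, had 3947 and 3524 against 1 and 3 (adjusted p = 1.52e-05). Egfl6 was 542-fold higher (adjusted p = 1.52e-05) and the sialyltransferase gene St6galnac4 was at least 174-fold higher (adjusted p = 8.49e-05). The non-coding RNA Snhg11 had 1691 and 1490 in BASC against 1 and 4 in Club cells. In the other direction, several genes that were abundant in Club cells had low values in BASC. Clca1, secreted by goblet cells, had 1 and 1 in BASC against 6830 and 10667 in Club cells (adjusted p = 0.000333), and the trefoil factor gene Tff2 was listed at 0 in BASC, at least 375-fold lower (adjusted p = 0.000997). Lactoferrin, encoded by Ltf, had 40 and 0 in BASC against 11097 and 4665 in Club cells (adjusted p = 0.00933). Fer1l6 was at least 397-fold lower, Sult1d1 at least 464-fold, Vtcn1 at least 251-fold and Crybg2 at least 242-fold, each listed at 0 in both BASC libraries. Ccdc129 and the membrane mucin gene Muc16 had 1 and 0 in BASC.

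The Club libraries also held markers of other airway cell types, which moved with the comparisons above. Of 23 multiciliated cell markers, 11 were lower in BASC than in Club cells and 12 were not called; 20 were lower when adjusted over the list alone (median log2 fold change -4.91, camera adjusted p = 8.06e-10, but adjusted p = 0.0855 with an estimated correlation). Sntn had 138 and 140 in Club cells and was listed at 0 in BASC and AT2. The cilia regulator gene Foxj1 had 795 and 825 in Club cells, 115 and 100 in BASC and 96 and 40 in AT2. Against AT2, BASC had a median of 1.18 for this list with no gene called by limma and 5 higher at an unadjusted p under 0.05 (camera adjusted p = 0.00175, and adjusted p = 0.240 with an estimated correlation). Of 7 goblet cell markers, 4 were lower in BASC than in Club cells and 3 were not called; 5 were lower when adjusted over the list alone (median -5.53, camera adjusted p = 5.49e-05, and adjusted p = 0.100 with an estimated correlation). Agr2, which folds mucins, was at least 94.7-fold lower in BASC, and Muc5ac was 46.7-fold lower. Of 20 interferon response genes, 3 were lower in BASC than in Club cells, also when adjusted over the list alone (median -2.54, camera adjusted p = 0.000624, and adjusted p = 0.115 with an estimated correlation). Ifit1 had 110 and 143 in Club cells and was listed at 0 in the other 4 libraries. The mesothelial marker Msln had 379 and 182 in Club cells, 1 and 2 in BASC and was listed at 0 in AT2.

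In all, 1022 genes were higher and 961 lower in BASC than in Club cells, by limma over 17721 genes. Without BASC replicate 1 the counts were 480 and 503, without BASC replicate 2 they were 506 and 441, without Club replicate 1 they were 657 and 196, and without Club replicate 2 they were 698 and 214. Of 97 differences named in the text, 80 and 78 were still called without BASC replicate 1 or 2, and of 85, 71 and 70 were still called without Club replicate 1 or 2. Cd24a was among those lost.

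AT2 cells were compared with Club cells to place the BASC values between the populations that each carry 1 of the reporters. This contrast called the most genes of the 3, with 1492 higher and 1720 lower in AT2. All 26 AT2 markers were higher in AT2 than in Club cells, also when adjusted over the list alone (median log2 fold change 4.38, camera adjusted p = 1.71e-39, and adjusted p = 0.0285 with an estimated correlation). Of 25 Club secretory markers, 23 were lower in AT2 and 2 were not called, with 24 lower when adjusted over the list alone (median -8.70, or -8.47 with genes at 0 set to their bound, camera adjusted p = 2.53e-25, and adjusted p = 0.0285 with an estimated correlation). Sftpc was 1455-fold higher in AT2 (log2 fold change 10.49, adjusted p = 4.64e-08), and Scgb1a1 was 2115-fold lower (-11.06, adjusted p = 1.83e-07). The secretoglobin genes Scgb3a1 and Scgb3a2 were 9461-fold and 3564-fold lower in AT2 (adjusted p = 0.000223 and 6.62e-06), and Muc5b was 5569-fold lower (adjusted p = 3.82e-06). Bpifa1, an antimicrobial protein gene of the airway surface, had 64511 and 25250 in Club cells against 1 and 5 in AT2 (adjusted p = 0.000605), and its relative Bpifb1 had 22921 and 18573 against 1 and 2 (adjusted p = 6.85e-05). Of 28 xenobiotic genes, 26 were lower in AT2 and Gstt1 was higher, also when adjusted over the list alone (median -5.09, or -4.90 with genes at 0 set to their bound, camera adjusted p = 2.83e-23, and adjusted p = 0.0285 with an estimated correlation). The call of Gstt1 (adjusted p = 0.0398) was lost in 10 alternatives, among them leaving out any of the 6 libraries.

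Of 18 cholesterol synthesis genes, 15 were higher in AT2 than in Club cells and 3 were not called, with 17 higher when adjusted over the list alone (median log2 fold change 1.76, camera adjusted p = 9.94e-11, but adjusted p = 0.252 with an estimated correlation). All 7 MHC class II genes were higher in AT2, also when adjusted over the list alone (median 6.27, camera adjusted p = 3.58e-09, but adjusted p = 0.129 with an estimated correlation). The class II genes H2-Ab1, with 2920 and 5744 in AT2 against 0 and 1 in Club cells, and H2-Eb1, at least 614-fold higher, were among the 10 largest differences. Of 20 fatty acid and phospholipid genes, 11 were higher and 1 was lower, with 12 higher and 3 lower when adjusted over the list alone (median 1.11, camera adjusted p = 1.93e-07, but adjusted p = 0.157 with an estimated correlation). The peroxisomal oxidase gene Acoxl had 7110 and 6704 in AT2 against 2 and 0 in Club cells (adjusted p = 1.48e-05), and the hexokinase-like gene Hkdc1 was at least 371-fold higher (adjusted p = 5.56e-05). Of 23 multiciliated cell markers, 19 were lower in AT2 and 4 were not called, with 20 lower when adjusted over the list alone (median -6.23, or -6.07 with genes at 0 set to their bound, camera adjusted p = 9.94e-11, but adjusted p = 0.0749 with an estimated correlation). Of 7 goblet cell markers, 6 were lower in AT2, also when adjusted over the list alone (median -8.33, or -6.86 with genes at 0 set to their bound, camera adjusted p = 3.50e-06, but adjusted p = 0.0817 with an estimated correlation). Of 15 Notch genes, 8 were lower in AT2 and 7 were not called, with 9 lower when adjusted over the list alone (camera adjusted p = 0.00173, but adjusted p = 0.129 with an estimated correlation). Of 23 Wnt pathway genes, 9 were higher in AT2 and 4 were lower, with 11 and 5 when adjusted over the list alone (median 0.69, camera adjusted p = 0.0180, but adjusted p = 0.257 with an estimated correlation). Ctnnb1, which encodes beta-catenin, was 1.96-fold higher in AT2 (adjusted p = 0.000453). Without AT2 replicate 1, AT2 replicate 2, Club replicate 1 and Club replicate 2 in turn, the genes higher in AT2 numbered 913, 902, 965 and 991. The genes lower in AT2 numbered 1121 without AT2 replicate 2, 574 without Club replicate 1 and 612 without Club replicate 2. Of 109 differences named in the text, 107 and 105 were still called without AT2 replicate 1 or 2, and of 96, 90 and 89 were still called without Club replicate 1 or 2.

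**Figure D2:**
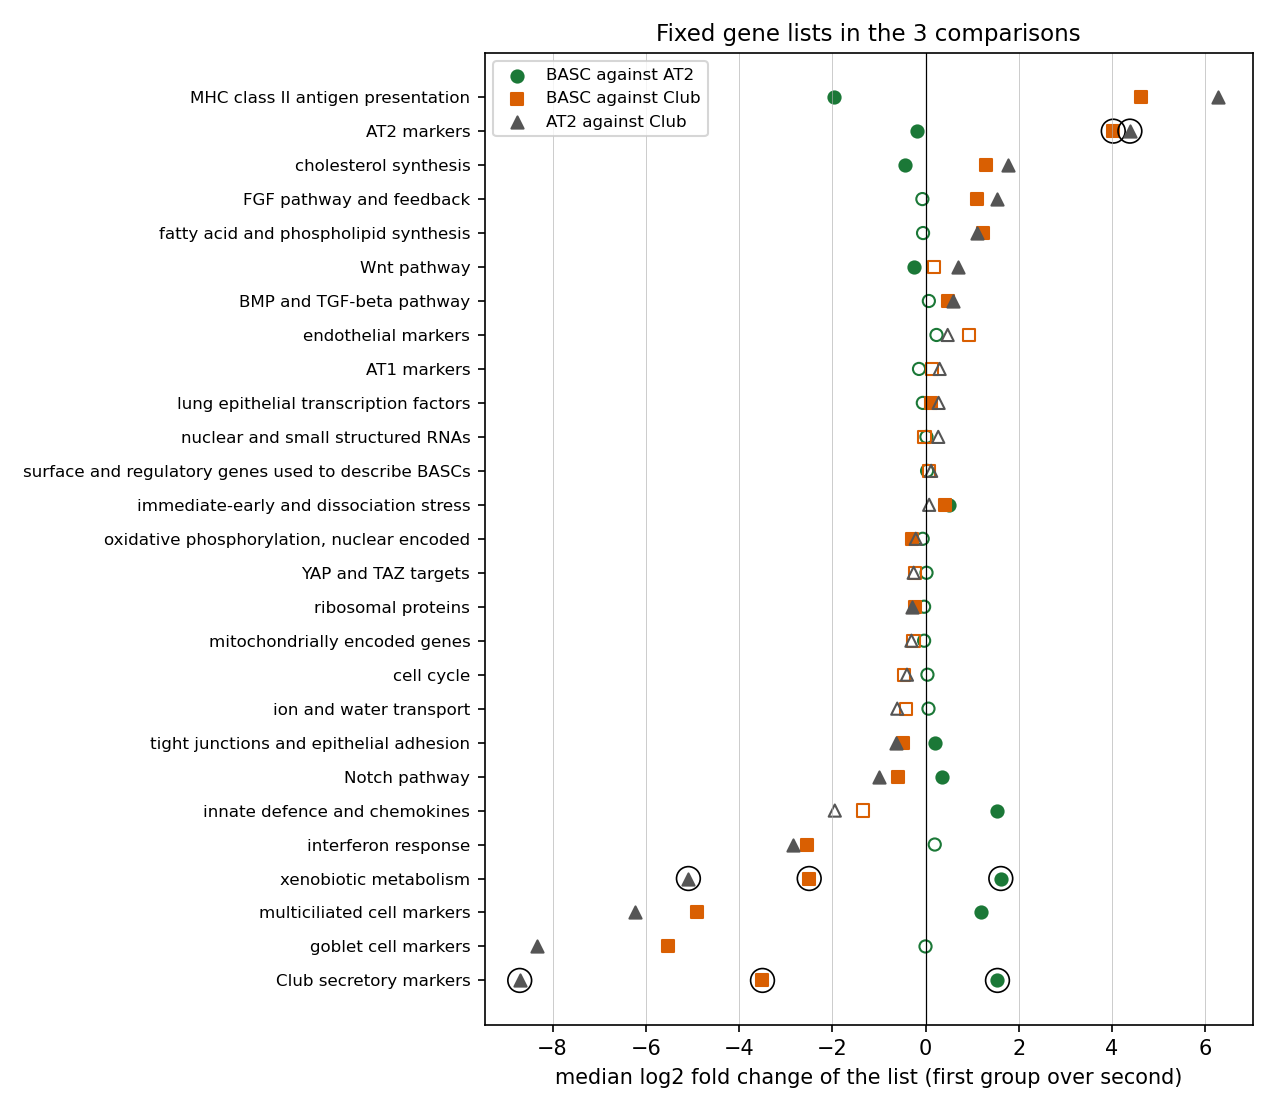
Median log2 fold change of each fixed gene list in the 3 comparisons. Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation, open points mark the others, and a black ring marks lists that also passed with an estimated correlation, which were the AT2, Club secretory and xenobiotic lists.

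BASC against both other populations asked which genes set these cells apart from AT2 and from Club cells at once. By limma, 4 genes were higher in BASC than in both, and 1 was lower than in both. Plk2 (ENSMUSG00000021701, chromosome 13, 110395046 to 110400844), a polo-like kinase gene induced by stress, was 5.31-fold higher than in AT2 (log2 fold change 2.42 ± 0.13, adjusted p = 0.000700) and 2.35-fold higher than in Club cells (adjusted p = 0.00167). Fam102b (ENSMUSG00000040339, chromosome 3, 108970997 to 109027607) was 3.08-fold higher than in AT2 (1.62 ± 0.16, adjusted p = 0.00980) and 6.64-fold higher than in Club cells (adjusted p = 8.95e-05). Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), an immediate-early transcription factor gene, was 1.99-fold and 2.32-fold higher (adjusted p = 0.0141 and 0.000668). Slc2a3 (ENSMUSG00000003153, chromosome 6, 122727809 to 122742745) had 494 and 349 in BASC against 0 and 0 in AT2 and 3 and 0 in Club cells. Trappc13 (ENSMUSG00000021711, chromosome 13, 104142149 to 104178469), a subunit gene of a vesicle tethering complex, had 238 and 245 in BASC, 699 and 599 in AT2, and 461 and 487 in Club cells (adjusted p = 0.0433 and 0.0303). Lists drawn independently at these sizes would share 5.65 and 0.759 genes. In 100 simulations of groups without a difference that shared these libraries, calls shared 0 genes, as at most 1 gene was called per direction. Lists of the observed sizes were taken by p from the same simulations, a comparison chosen after the result was seen. They shared means of 27.9 and 10.6 genes, and the observed 4 and 1 were not above these. The simulations leave out the differences between the groups, while 95 of the 98 genes higher in BASC than in AT2 were also higher in Club cells. The means therefore cannot decide whether an overlap of 4 and 1 exceeds chance. Without BASC replicate 1 or BASC replicate 2, limma found 0 genes higher than both, without AT2 replicate 1 it found 2, without AT2 replicate 2 it found 3, and without Club replicate 1 or 2 it found 6. Trappc13 was not called against both when any of the 6 libraries was left out.

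Immediate-early and dissociation stress genes lay higher in BASC than in AT2 and in Club cells by the list test at its preset correlation. Against AT2, Egr1 was called among 20 listed genes and 19 were not, with 9 higher when adjusted over the list alone (median log2 fold change 0.50, camera adjusted p = 7.29e-07, but adjusted p = 0.289 with an estimated correlation). Against Club cells, Egr1, Fosb and Junb were higher and 17 were not called, with 10 higher when adjusted over the list alone (median 0.42, camera adjusted p = 3.63e-06, but adjusted p = 0.259 with an estimated correlation). Fosb had 10858 and 13879 in BASC, 7493 and 9534 in AT2, and 6919 and 6986 in Club cells.

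Most differences between BASC and a single population followed the contrast between AT2 and Club cells. Of the 98 genes higher in BASC than in AT2, 95 were also higher in Club cells than in AT2, where independent lists would share 9.51. The 3 others were Slc2a3, Egr1 and Fam102b. Of the 14 genes lower in BASC than in AT2, 13 were higher in AT2 than in Club cells (1.18 for independent lists), with Trappc13 as the exception. Of 1022 genes higher in BASC than in Club cells, 917 were higher in AT2 than in Club cells, and of 961 lower, 836 were lower in AT2, against 86.0 and 93.3 for independent lists. In the 100 simulations without a difference calls shared 0 genes, and lists of the observed sizes shared means of 68.9, 5.72, 414 and 279 genes, with 82, 10, 448 and 310 as the highest. The simulations leave out the effects and the independent lists leave out the shared libraries, so part of the excess may come from the shared libraries.

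BASC stood nearer to AT2 than to Club cells on the log2 scale. With Club cells at 0 and AT2 at 1, the median position of BASC over 712 AT2-high genes was 0.814, with 0.833 in BASC replicate 1 and 0.802 in BASC replicate 2, and 86.4% of these genes lay nearer to AT2. Over 1177 Club-high genes the median was 0.714, with 0.694 and 0.716 in the BASC replicates, and 69.8% lay nearer to AT2. The quartiles were 0.451 and 1, and a gene listed at 0 in both BASC and AT2 takes the position 1 whatever its Club level. This median thus depended on how low values were treated: it was 0.639 with a filter at 50 and 0.766 with a pseudocount of 10. As a share of the level itself, the 33 abundant Club-high genes had a median of 5.77% of their Club level in BASC replicate 1 and 8.00% in BASC replicate 2, with -0.0457% for Clca1 and 53.6% for Cd24a over both libraries, after subtraction of the AT2 level. The 45 abundant AT2-high genes had medians of 71.4% and 62.0% of their AT2 level.

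**Figure D3:**
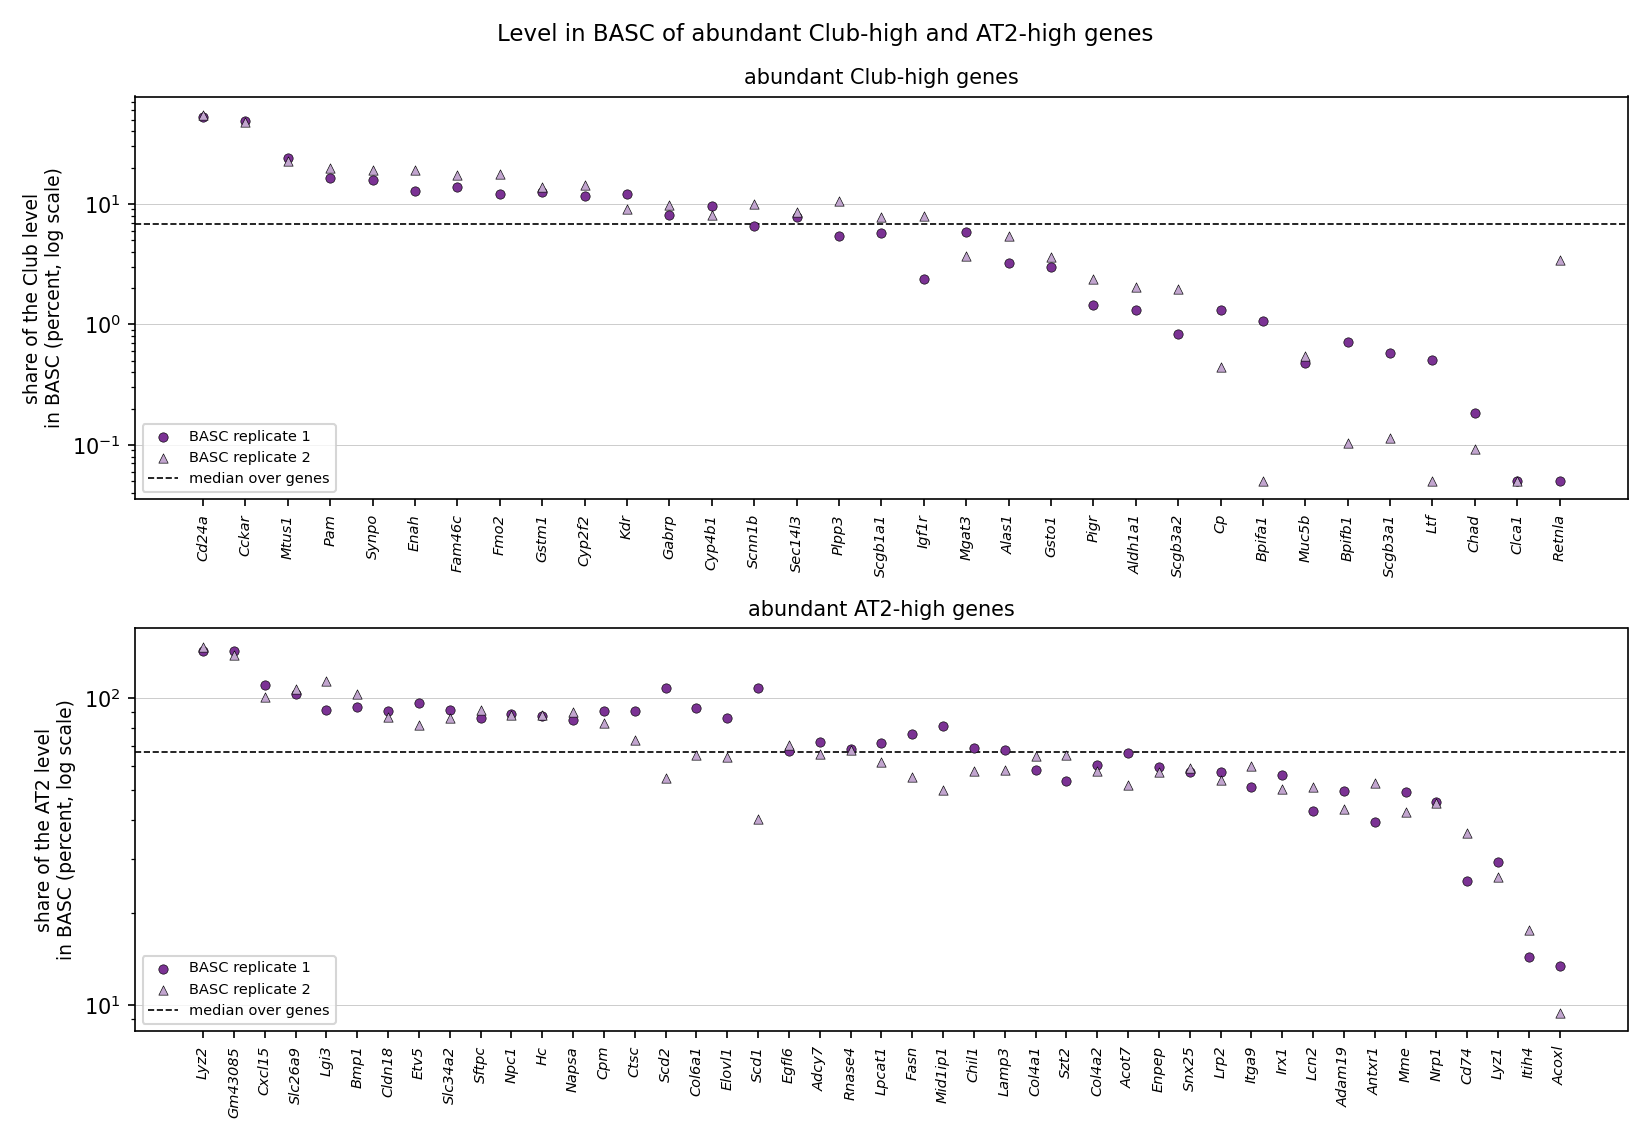
Level of abundant genes in each BASC library, as a percent of the Club level for Club-high genes and of the AT2 level for AT2-high genes. Each point is a gene in a BASC library, shares under 0.05% are drawn at 0.05, and dashed lines are medians over genes.

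Genes proposed in the field as surface markers or regulators of BASC gave few calls. Of 12 listed genes, 10 were tested, while Cd34 and Abcg2 had no entry in the deposited values. Of those tested, Cd24a was the only gene called between BASC and AT2 and between BASC and Club cells, also when adjusted over the list alone. Ly6a, which encodes Sca-1, had 32 and 3 in BASC, listed values of 0 in AT2, and 243 and 206 in Club cells (BASC against AT2, adjusted p = 0.294). Bmi1, a Polycomb gene, had 748 and 535 in BASC, 693 and 1070 in AT2, and 421 and 384 in Club cells. For AT1 markers, 4 were higher and 4 lower of 20 in BASC against Club cells (6 and 6 when adjusted over the list alone; camera adjusted p = 0.507), with a median log2 fold change of 0.13 and a mean of -0.50. Ager was 5.42-fold higher in BASC than in Club cells (adjusted p = 0.000107), while the sodium channel gene Scnn1g was 16.5-fold lower (adjusted p = 0.000155) and Pdpn was listed at 0 in BASC against 561 and 457 in Club cells. Of 23 cell cycle genes, limma called none between BASC and AT2, with 3 higher and 1 lower at an unadjusted p under 0.05 and 1 higher when adjusted over the list alone. Bub1, a mitotic checkpoint gene, was higher in BASC than in Club cells (adjusted p = 0.0416), with 71 and 68 in BASC against 8 and 0. That call was not kept when adjusted over the list alone and was lost in 9 alternatives, which included leaving out either BASC library, either AT2 library or Club replicate 2.

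Markers of cells that the depletion and the sort should remove were in part missing from the deposited values. For a gene without an entry, absence from the cells cannot be concluded. Of 18 hematopoietic markers, 11 had no entry, 3 fell under the filter and 4 were tested. Limma called none of the 4 in any comparison. At an unadjusted p under 0.05, 1 was higher in BASC and 1 in AT2 than in Club cells, the latter also when adjusted over the list alone. Cd68 had between 114 and 280 in the 6 libraries. Of 15 endothelial markers, 5 had no entry, 2 fell under the filter and 8 were tested. Between AT2 and Club cells, limma called 1 of them higher and 3 lower in AT2. Beside Kdr, the gene Esam had 677 and 419 in BASC, 1087 and 964 in AT2 and 2 and 3 in Club cells, while Calcrl had 92 and 50 in Club cells. Fibroblast and smooth muscle markers (4 of 15 tested), basal cell markers (3 of 10), neuroendocrine markers (3 of 11) and the erythroid gene Alas2 gave no call by limma over all genes in any comparison. At an unadjusted p under 0.05 and when adjusted over the list alone, 1 neuroendocrine marker was lower in BASC than in AT2, and Alas2 was lower in BASC than in Club cells. Another call at an unadjusted p alone was 1 neuroendocrine marker lower in BASC than in Club cells. Their values were low, such as 27 and 8 for Col1a1 in BASC, 16 and 0 for Krt17 in BASC, 135 and 74 for Cplx2 in BASC and 34 and 30 for Alas2 in Club cells. Xist lay between 11047 and 14512 in the 6 libraries.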

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

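The fit with voom weights was chosen only after the result was seen; the other alternatives were planned. Counts of genes are given as higher and lower in the first-named group. For BASC against AT2 (98 and 14), a filter at 50 gave 204 and 61, a fit of only the groups compared gave 60 and 45, and a robust prior gave 155 and 41. A pseudocount of 10 gave 40 lower, array weights gave 6 lower and voom weights on the estimated reads gave 169 lower. For BASC against both (4 and 1), a pseudocount of 10 gave 9 higher, a filter at 50 gave 9 and 6, only the groups compared gave 7 and 0, a robust prior gave 8 and 3, voom weights gave 25 and 2, and no filter and array weights gave 0 lower each. A filter at 50 tests fewer genes and a fit of only 2 groups rests on fewer samples; for the others the cause was not tested. The median position over Club-high genes (0.714) moved to 0.688 with a pseudocount of 0.5, 0.766 with a pseudocount of 10, 0.695 without a filter, 0.639 with a filter at 50, 0.645 with a robust prior, 0.698 with a log2 fold change of at least 1 and 0.623 over the fixed Club markers. Over AT2-high genes (0.814) it moved to 0.778 with a pseudocount of 10, 0.779 with only the groups compared and 0.951 over the fixed AT2 markers, and the cause was not tested. With an estimated correlation, the lists past the threshold numbered 2, 3 and 3 in the 3 comparisons. The other alternatives kept each count within 1.5 times its value. The predicted gene Gm26917 went from 0.45 to -0.45 on the log2 scale in BASC against Club cells and from 0.15 to -0.63 in AT2 against Club cells under quantile normalization, and the cause was not tested. Over 251 called differences of named genes, 4168 of 4462 repeats gave the same direction and call. Calls lost in 7 or more alternatives were those of Muc5ac (11), Palm2, Pkib and Trappc13 (10 each), Gsta3 (9), Clic3 (8), Ciita and Hes1 (7 each) in BASC against AT2, Bub1 (9) and mt-Nd5 (7) in BASC against Club cells, and Gstt1 (10) in AT2 against Club cells.

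Leaving out each sample in turn gave 3 to 100 genes higher and 0 to 27 lower for BASC against AT2, 480 to 913 and 196 to 975 for BASC against Club cells, 902 to 1459 and 574 to 1832 for AT2 against Club cells, and 0 to 6 and 0 to 0 for BASC against both. The lone sample of a group was then assumed to vary like the other groups. Whether the changes came from the smaller number of samples or from the sample left out, the cause was not tested. Positions ranged from 0.792 to 0.843 over AT2-high and from 0.539 to 0.722 over Club-high genes, and lists past the threshold in BASC against AT2 from 7 to 11. With the replicate number as a replicate block, the counts were 102 and 18, 1004 and 857, 1453 and 1592, and 6 and 1, and the Club-high position was 0.686; the 1 gene lower than both was then another than Trappc13, which lost its call against AT2. Deviations of equally numbered replicates correlated across genes at 0.006 to 0.012 between groups, which gave no sign of pairing. Genes with few reads varied widely between replicates and can weaken such a correlation, so these low values do not exclude pairing. The planned fits with edgeR and DESeq2 were not run, because whole reads could not be recovered exactly, and list tests and positions were not computed with voom weights.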

Other observations

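All 4 tests weighed below were chosen only after the result was seen.

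Among the 98 genes higher in BASC than in AT2, the BASC level had a median of 31.5% of the Club level, with quartiles of 12.7% and 54.2%. A choice of genes higher in BASC favours high shares. The 33 abundant Club-high genes, chosen by AT2 against Club cells, had a median share of 6.89%, taken as the mean of the medians of both BASC libraries. That share was computed after subtraction of the AT2 level and for abundant genes only. The values therefore also differ in measure and in set of genes. Of the 98 genes, 12 stood at or above their Club level. Among these, Slc2a3, Plk2, Egr1, Fam102b and Creb3l1 were named by the rule. Clic3, Pkib, Btbd11, Otud1, Aox3, Btc and Palm2 were named after their values were seen. Of 18 genes of tight junctions and epithelial adhesion, 6 were lower and 2 higher in BASC than in Club cells (8 and 2 when adjusted over the list alone; camera adjusted p = 0.00625, but adjusted p = 0.147 with an estimated correlation). Cldn18, an alveolar claudin gene, was 34.6-fold higher in BASC than in Club cells, and Krt19 was 6.02-fold lower. Against AT2, the tight junction list had a median log2 fold change of 0.20 without a called gene (camera adjusted p = 0.0195, and adjusted p = 0.240 with an estimated correlation). Of 21 genes of innate defence, 7 were higher and 9 lower in BASC than in Club cells (camera adjusted p = 0.613): complement C3 was 5.15-fold lower and Chil1 was 7.57-fold higher. Against AT2, the innate defence list had a median log2 fold change of 1.54, or 1.35 with genes at 0 set to their bound (camera adjusted p = 0.0185, and adjusted p = 0.240 with an estimated correlation). Of 17 ion and water transport genes, 2 were higher and 6 lower in BASC than in Club cells (camera adjusted p = 0.202, or 0.0465 under quantile normalization), with the chloride transporter gene Slc26a9 at 8.91-fold higher and the chloride channel gene Ano1 at 13.2-fold lower. Of 13 YAP and TAZ targets, Areg was higher and Ccnd1 lower in BASC than in Club cells (camera adjusted p = 0.848).

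Few genes of housekeeping lists were called. Of 24 ribosomal protein genes, Rps19 was higher in BASC than in Club cells, while the list's median was -0.23 (camera adjusted p = 0.00625, but adjusted p = 0.441 with an estimated correlation). Of 20 nuclear-encoded genes of oxidative phosphorylation, Cox4i1 was lower in BASC than in Club cells (camera adjusted p = 0.0464, or 0.0567 under trimmed-mean scaling, but adjusted p = 0.277 with an estimated correlation). Of 7 mitochondrially encoded genes tested, mt-Nd5 was lower in BASC than in Club cells (camera adjusted p = 0.123, or 0.00289 under quantile normalization, where the median went from -0.26 to -0.44). Between BASC and AT2 limma called none of these genes, with 1 ribosomal gene higher, 1 nuclear-encoded gene of oxidative phosphorylation higher and 2 lower at an unadjusted p under 0.05; the median of the ribosomal list changed sign under quantile normalization and under scaling to a common total, and that of the mitochondrial list under the latter. Of 11 nuclear and structured RNAs, Malat1 was 1.61-fold higher in BASC than in Club cells and Snhg11 was also higher, with a list median of -0.02 and a mean of 1.06 (camera adjusted p = 0.214). Among sex-linked genes, Xist and Tsix were the genes tested, and neither was called in any comparison.

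Club-high genes stood in BASC at unequal shares of their Club level, after subtraction of the AT2 level, such as 0.138% for Chad, 0.345% for Scgb3a1, 6.75% for Scgb1a1, 12.9% for Cyp2f2 and 53.6% for Cd24a. A single fixed admixture of the sorted Club population (doublets, carry-over or free RNA) would bring all abundant Club transcripts at 1 share, yet 60.6% of 33 abundant genes lay more than 2-fold off the median share in both BASC libraries, where 24.2% differed that much between the libraries and simulated mixtures reached at most 3.03%. The order of the shares across genes was alike in both libraries (rho across genes 0.942, at most 0.535 in simulated mixtures), although genes are not independent replicates. An admixture of a subset of Club cells with a profile of its own stays open: 78.6% of 14 Club secretory and xenobiotic genes lay more than 2-fold off their own median of 2.49%, but the profile of such a subset was not measured, so it cannot be told apart from a partial Club programme within BASC. That BASC express part of this programme is a hypothesis that was not tested here.

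AT2-high genes also stood at unequal shares of their AT2 level, after subtraction of the Club level. Shares ranged from 11.4% for Acoxl, 15.9% for Itih4 and 27.6% for Lyz1 to 145% for Lyz2. Reads of Lyz1 and Lyz2 may be split unevenly between these paralogs. The quartiles were 55.8% and 88.0%, and 6.67% of the 45 genes lay more than 2-fold off the median share in both BASC libraries. Simulated mixtures of the AT2 and Club profiles reached at most 0%, and 2.22% of the genes differed that much between the libraries. The order of the shares was partly alike in both libraries (rho across genes 0.745, at most 0.597 in simulated mixtures). A dilution of AT2 cells by 1 fixed share of other cells would lower all 45 abundant genes alike. Yet after each library was centred over these genes, both BASC libraries lay above or below both AT2 libraries for 30 of them, where chance gives 15. The other splits of the 4 libraries gave 13 and 2. Each gene falls to only 1 split, so these counts are what the 30 left over and no separate check. They were also uneven, so the chance level of 15 may not hold for these genes. With the AT2 level at 66.7% over both libraries, Club cells as the remainder would bring their abundant genes at far more than the median share of 6.89% seen for Club-high genes. A type of cell not sorted here would bring abundant genes of its own, but 0 genes had at least 500 in both BASC libraries and at least 3 times the value of every other library. Slc2a3, with 494 and 349 in BASC, fell under the floor of 500. Genes that the AT2 or Club libraries held at similar levels could not pass this bound. Club cells mixed into AT2 at that share would give 103 genes under a looser bound, set against the AT2 libraries alone. These counts are not alike, so the count of 0 does not exclude such a type of cell. The genes vary together, so they are not independent, and a small share of other cells, a BASC gate that took a subset of AT2 cells and a difference in expression were not tested and stay open.

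Of 20 immediate-early and dissociation stress genes, 18 had higher means in BASC than in both other populations, where chance places a gene highest in BASC in 1 of 3 cases, but limma called only 1 of them, Egr1, against both. A stronger response to dissociation and sorting in the BASC libraries may account for this, but the count of 18 restates the pattern and decides nothing, so it cannot be told apart from a difference between the cell populations. The listed genes respond together, so they are not independent. The labels give no time or order of sorting, and a higher level of these genes in BASC in the lung was not tested and stays open.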
